A study of Medicago truncatula with 4 samples.

How the data were processed

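Small RNA was sequenced from *Medicago truncatula* leaf in 4 libraries, 2 with HD adapters and 2 with standard Illumina adapters, per the labels' adapter entries. The labels' extract protocol names standard adapters for every library. The grouping follows the adapter entry of each sample. The plants grew at 25 °C by day and 18 °C by night with 16 h of light, per the labels. HD adapters carry 4 random bases at each ligating end.

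The authors deposited, for each library, a list of distinct read sequences, each joined to its raw read count in the same cell, a whole number of 1 or more, with no other normalization. Adapter trimming and the collapse of equal reads are read from the files themselves. The trimming tool, quality filter and any match to a genome are not given in the sources used here. The files hold reads from 17 nt up to 32 nt with HD and up to 40 nt with standard adapters. Exact listed miRNA took 816467 and 946162 HD reads, against 1 and 0 with 4 extra bases on each side. The deposited HD reads thus lacked the random bases, and none were removed here. Bases are written as DNA, with T for U. No genome was used, so no positions or gene annotations are given, and a sequence that several loci encode counts as 1.

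Depth was 14362079 and 18052071 reads in HD and 21571174 and 34782490 reads in standard libraries, so that the widest 95% Wilson interval of a library share was ± 0.0259 percentage points. The spread between libraries, not the depth, limits the shares. Of distinct sequences, 80.0% and 77.3% were read once in HD and 68.6% and 75.2% in standard libraries. The reads hold no molecular identifiers. A count of 0 was given a floor of 3 reads over the group.

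Sequences were tested if they had at least 0.505 reads scaled to a library of 1000000 (RPM, here 10 reads at the median library) in 2 libraries and at least 15 reads over all 4, which left 168837. Counts were scaled by trimmed means of M-values (30% of log ratios and 5% of mean levels trimmed), with factors of 0.847 and 0.898 for HD and 1.20 and 1.10 for standard libraries. Differences were tested with limma voom and Benjamini-Hochberg adjustment at 0.05, with the adapter type as the only term. This replaces the quasi-likelihood count test fixed before the data were examined, because sequence and count share a cell of text and the column could not be recorded as a plain count column. The prior degrees of freedom were 4.35. On simulated counts for the same 168837 sequences and libraries with a dispersion of 0.119, the test recovered 0, 2, 15 and 27 of 50 sequences changed by 2-, 4-, 8- and 16-fold, with 1 false call. With no change simulated it made 0 calls, and 4.64% of p-values lay under 0.05. Far fewer sequences were changed in the simulation than the 103353 called in the data, and all shared 1 dispersion. It therefore gives neither the recovery nor the rate of false calls in the data. Reads were also summed over 96 classes of length and first base with at least 10 reads, scaled to library totals and tested with limma voom. Shares of reads were compared by exact two-sided permutation tests. Distinct sequences at equal depth are the expected number in 14362079 reads drawn without replacement. Base frequencies at the first and last 3 positions were tested with Fisher's exact test and adjusted over 48 tests.

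Before the data were examined, lists were written of 34 conserved miRNA, 7 legume miRNA of the 22-nt group, 7 strands of the opposite arm and 2 trans-acting siRNA, matched by exact sequence. Further lists held the starts of 4 tRNA, the 2 adapter sequences (any 12 bases) and miRNA of *Arabidopsis* and of animals as a check for reads of other origin. Named sequences followed a rule also fixed then. It took the 20 list members with the highest mean RPM. It took the 6 sequences with the largest log2 change in each direction among those past the threshold with at least 50 RPM in the higher group, skipping any that shared 16 bases in a row with one taken. It took the 3 most abundant sequences of each group. Fold differences are ratios of mean RPM, while log2 values come from the fit with its scaling.

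Alternatives were other scalings, looser and stricter read filters, reads of 20 to 25 nt only, variants summed over their first 18 bases, a replicate block, and each library left out in turn. Chosen after seeing the data were limma-trend, leaving out reads with adapter bases, a block with crossed numbers, and 3 further settings of the class test. In the fits that leave out a library, the lone library of its group is assumed to vary like the other group. The read filter there asked for as many libraries as the smaller group held. More sequences were therefore tested, 230079 to 262495, and the scaling changed with them. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and ViennaRNA 2.7.2, and R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8).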

Results

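Small RNA libraries from *Medicago truncatula* leaf were made with HD adapters, whose ligating ends carry random bases, or with standard Illumina adapters of fixed sequence. Each adapter type was used for 2 libraries, from plants grown without a specific treatment. None of the RNA was treated with TAP, an enzyme that turns capped or triphosphate 5′ ends into ends that can be ligated. The HD libraries held 14362079 and 18052071 reads and the standard libraries 21571174 and 34782490 reads, collapsed to distinct sequences. Over the 4 libraries there were 22609496 distinct sequences, of which 506718 (2.24%) were read in every library. Among tested sequences, log2 abundances correlated at r = 0.872 between the HD libraries and r = 0.938 between the standard libraries, against 0.215 to 0.297 for pairs of libraries with different adapters (correlations across sequences, which are not independent replicates). A sequence could pass the read filter through the 2 libraries of a single adapter type, so the filter can widen this contrast. Nothing in the labels says that replicates came from separate plants or extractions, so p-values measure only the spread between these libraries, which may be technical. An exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.33.

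The libraries were set side by side to see which small RNA populations each adapter type recovers. The first comparison was by size class. Reads of 24 nt, the length of most heterochromatic siRNA in plants, were the largest class in every library, at 46.6% ± 0.643 of reads in HD libraries and 43.5% ± 2.38 in standard libraries (SD, n = 2 each). Reads of 21 nt, the length of most miRNA, made up 13.8% ± 0.663 with HD adapters and 17.6% ± 4.37 with standard adapters. The 22-nt class stood at 8.05% ± 0.375 against 5.72% ± 0.559, and the 23-nt class at 10.4% ± 0.483 against 7.95% ± 0.0964. For each of these 4 classes both HD libraries lay on the same side of both standard libraries, with an exact permutation p of 0.33, the smallest possible. At 24 nt this separation was lost among reads of 20 to 25 nt (a difference of 1.43 percentage points, exact permutation p = 1) and without the 10 most abundant sequences of each library (0.397, exact permutation p = 0.667). At 21 nt it was lost without reads holding adapter bases (exact permutation p = 0.667), and without the 10 most abundant sequences the difference turned to 1.62 percentage points (exact permutation p = 0.667). Shares of the 22-nt and 23-nt classes were not recomputed without abundant sequences. Within the 22-nt class, reads starting with T (U in the RNA) made up 51.7% ± 0.731 in HD and 39.7% ± 0.0296 in standard libraries. Within the 24-nt class, A was the most frequent first base with both adapters, at 42.4% ± 0.00715 and 38.9% ± 2.12, while G stood at 23.2% ± 0.454 against 17.01% ± 0.417 and C at 13.9% ± 0.445 against 19.1% ± 0.521. Reads of 17 to 19 nt took 4.31% ± 2.66 of HD and 9.14% ± 0.153 of standard libraries. The 2 HD libraries lay far apart there, at 6.20% and 2.43%. Standard replicate 2 set much of the gap in the 24-nt and 21-nt classes. Without it the HD minus standard difference went from 3.11 to 1.43 percentage points at 24 nt and from -3.81 to -0.73 at 21 nt.

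**Figure D1:**
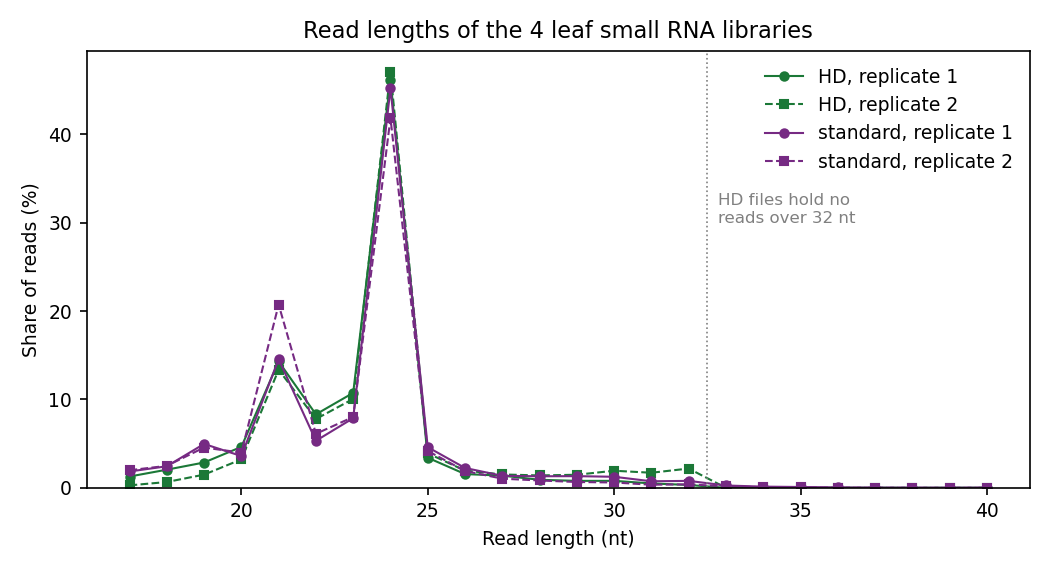
Share of reads (%) at each read length (nt) in the 4 libraries, 1 line per library, HD in green and standard in purple. The 24-nt peak was at 46.2% and 47.1% in HD and at 45.2% and 41.8% in standard libraries, and standard replicate 2 reached 20.7% at 21 nt, where the other libraries lay between 13.4% and 14.6%.

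Of 96 classes of length and first base, limma voom called 43 at an adjusted p under 0.05. Reads of 33 to 40 nt made up 32 of them, and no HD read was longer than 32 nt, a limit of the HD files. The other 11 classes were 19-nt C, 21-nt A and T, 22-nt T, 23-nt A and G, all 4 first bases of 24 nt, and 30-nt G. The 22-nt T class took 4.16% ± 0.253 of HD reads and 2.27% ± 0.223 of standard reads, and the 24-nt G class 10.8% ± 0.361 and 7.40% ± 0.223. The 19-nt C class took 0.606% ± 0.218 of HD and 2.88% ± 0.283 of standard reads. The class calls rest on how the spread is modelled: voom found no spread between classes beyond its weights, and over classes of 17 to 32 nt with a spread estimated without weights, limma called 0 of 64, with 9 at an unadjusted p under 0.05 (smallest adjusted p = 0.260).

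Library complexity was compared at one depth, 14362079 reads. There, HD libraries held 1 distinct sequence for more of their reads, 41.1% ± 1.001 against 32.7% ± 0.911 (SD, n = 2 each, exact permutation p = 0.33). The 10 most abundant sequences took 6.16% ± 0.185 of HD and 11.7% ± 3.27 of standard reads (exact permutation p = 0.33). Their difference of -5.59 percentage points was -3.27 without standard replicate 2. With sequences read at least 2 times only, the difference in distinct sequences turned from 8.43 to -3.38 percentage points. Sequences read once were dropped at each library's full depth, which was greater in standard libraries. This turn therefore cannot be told apart from an effect of depth.

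The central comparison asked which sequences each adapter type favoured. Of 168837 sequences with enough reads to test, 103353 (61.2%) differed between the adapter types at an adjusted p under 0.05 by limma voom, 54708 higher in HD and 48645 higher in standard libraries. Which direction held more calls depended on the settings. With library totals as the scaling 50043 were higher in HD and 59513 in standard libraries, and with at least 10 reads over the 4 libraries as the filter 151563 and 160850. A change of at least 4-fold was found for 90179 of the 103353. There were 11003 sequences higher in HD libraries with no read in either standard library. Another 8330 were higher in standard libraries with no HD read, 8030 of them within 17 to 32 nt. Short sequences leaned towards standard adapters, with 56.0% of tested 17-nt sequences higher there and 7.31% higher in HD libraries. The 24-nt sequences split into 35914 higher in HD and 33862 higher in standard libraries, of 112181 tested. Among 23-nt sequences 4672 were higher in HD and 2708 in standard libraries. All of these changes are relative to the scaling. The median log2 change of HD over standard across tested sequences was -0.14 with the TMM scaling used, -0.53 with library totals only and 0.01 with median-of-ratios factors.

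Listed miRNA as a group were read well with both adapters but in different proportions. Of the 38 members of the miRNA lists that could be tested, 23 were higher in HD and 4 higher in standard libraries, and 11 did not pass the threshold. Adjusted over the list alone the counts were also 23 and 4. Reads identical to a list member took 5.46% ± 0.314 of HD and 7.30% ± 2.76 of standard libraries (exact permutation p = 0.667). Without standard replicate 2 that difference turned from -1.84 to 0.115 percentage points, so it did not hold up against the spread between replicates.

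Among conserved miRNA, 18 of 29 tested members were higher in HD, 3 were higher in standard libraries and 8 did not pass, with the same counts adjusted over the list alone. The largest change among those named was in miR167d, a regulator of auxin response factors, at 8969.6 ± 3102 reads scaled to a library of 1000000 (RPM) in HD and 115 ± 15.3 in standard libraries (SD, n = 2 each). This was a 78.2-fold difference (log2 6.65 ± 0.49 SE, limma adjusted p = 0.000286). Standard libraries read miR167d mainly with 1 extra 3′ base, in 86.2% ± 0.136 of exact and extended reads against 39.2% ± 3.14 in HD libraries, and with all reads that share its first 18 bases summed, a sum that also holds miR167a, the difference was log2 4.11 ± 0.49. The GRAS-targeting miR171b followed at 93.6 ± 66.0 against 1.87 ± 0.169 RPM (log2 5.82 ± 0.64, limma adjusted p = 0.000556). Another regulator of auxin response factors, miR160, was higher in HD libraries by log2 3.66 ± 0.67. So were miR172a, which targets AP2-type genes (log2 3.37 ± 0.44), miR319, which targets TCP genes (3.05 ± 0.51), and miR398b, which targets copper superoxide dismutase (2.97 ± 0.72). The Dicer regulator miR162 rose by log2 2.11 ± 0.43 with HD adapters and the NAC regulator miR164 by 1.27 ± 0.44.

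The growth-regulating-factor family of targets is shared by miR396a and miR396b, whose first 18 bases are the same. The b form was 6.19-fold higher in HD libraries, at 3553 ± 152 against 574 ± 120 RPM (log2 3.04 ± 0.45, limma adjusted p = 0.00187). The a form stood at 11686 ± 1763 against 15780.4 ± 9610 (log2 0.10 ± 0.60, limma adjusted p = 0.892), and its direction turned with library totals as the scaling, to -0.29. The 3 conserved miRNA higher in standard libraries were miR159, miR166 and miR157. The MYB regulator miR159 stood at 20392 ± 9022 RPM with standard and 4096 ± 156 with HD adapters (log2 -1.85 ± 0.53, limma adjusted p = 0.0227). For miR166, a regulator of HD-ZIP genes of leaf polarity, the values were 11949 ± 7718 and 1823 ± 723 (log2 -2.20 ± 0.66, limma adjusted p = 0.0273). Its partner strand, miR166 5p, stood at 5599 ± 1233 and 5890.1 ± 1162 (log2 0.47 ± 0.47, limma adjusted p = 0.412). The ARGONAUTE regulator miR168 was read at 12567 ± 356 with standard and 4717 ± 875 with HD adapters, with a limma adjusted p of 0.0931 and log2 -1.03 ± 0.46. The SPL regulator miR156 had 3222 ± 419 and 4157 ± 1757 RPM in the same order (log2 0.70 ± 0.51, limma adjusted p = 0.268). The 21-nt form of miR319 had 146 ± 81.4 and 162 ± 24.7 (log2 0.66 ± 0.56, limma adjusted p = 0.3335).

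The legume list of the 22-nt group, most of which target disease resistance genes of the NB-LRR class, went both ways. Some of its entries were shorter than 22 nt. Of 5 tested members 3 were higher in HD, 1 was higher in standard libraries and 1 did not pass, and the counts adjusted over the list alone were the same. Together the list took 6105 and 7074 RPM in HD libraries and 699 and 655 in standard libraries. There were 15.005 times as many reads of miR1507 with HD adapters, 2254 ± 232 against 150.2 ± 15.2 RPM (log2 4.30 ± 0.43, limma adjusted p = 0.000405). For miR2118 the difference was 10.1-fold, at 4221 ± 420.2 against 419 ± 55.3 (log2 3.73 ± 0.43, limma adjusted p = 0.000651). The other member higher in HD libraries was the 21-nt form of miR1509, at 7.61 ± 1.22 against 0.965 ± 0.471 RPM. The 22-nt form of miR1509 stood at 93.3 ± 35.3 against 54.7 ± 5.14, with a limma adjusted p of 0.0756. The member higher in standard libraries was miR1510, matched as a 21-nt sequence, at 52.0 ± 4.41 against 13.4 ± 4.33 (log2 -1.60 ± 0.47, limma adjusted p = 0.0244).

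Of the 4 opposite-arm strands tested, 2 were higher in HD and 2 did not pass, also when adjusted over the list alone. The strand miR390 3p was 59.9-fold higher in HD libraries, at 45.5 ± 14.004 against 0.760 ± 0.302 RPM, and miR396 3p was 3.41-fold higher. For miR168 3p the values were 632 ± 128 with HD and 1390 ± 131 with standard adapters (log2 -0.75 ± 0.45, limma adjusted p = 0.184). Of the trans-acting siRNA that target auxin response factors, the 2 exact listed forms had 1 read in all, in HD replicate 1. Reads that share the first 18 bases of one of them, D7, were present in every library, at 26.9 ± 7.74 RPM in HD and 25.2 ± 7.76 in standard libraries (log2 0.26 ± 0.44, limma adjusted p = 0.631). The members miR157, at 2.41 ± 0.354 RPM in HD and 10.02 ± 1.89 in standard libraries, the 21-nt form of miR1509, miR1510, miR390 3p and miR396 3p were named after their values were seen.

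**Figure D2:**
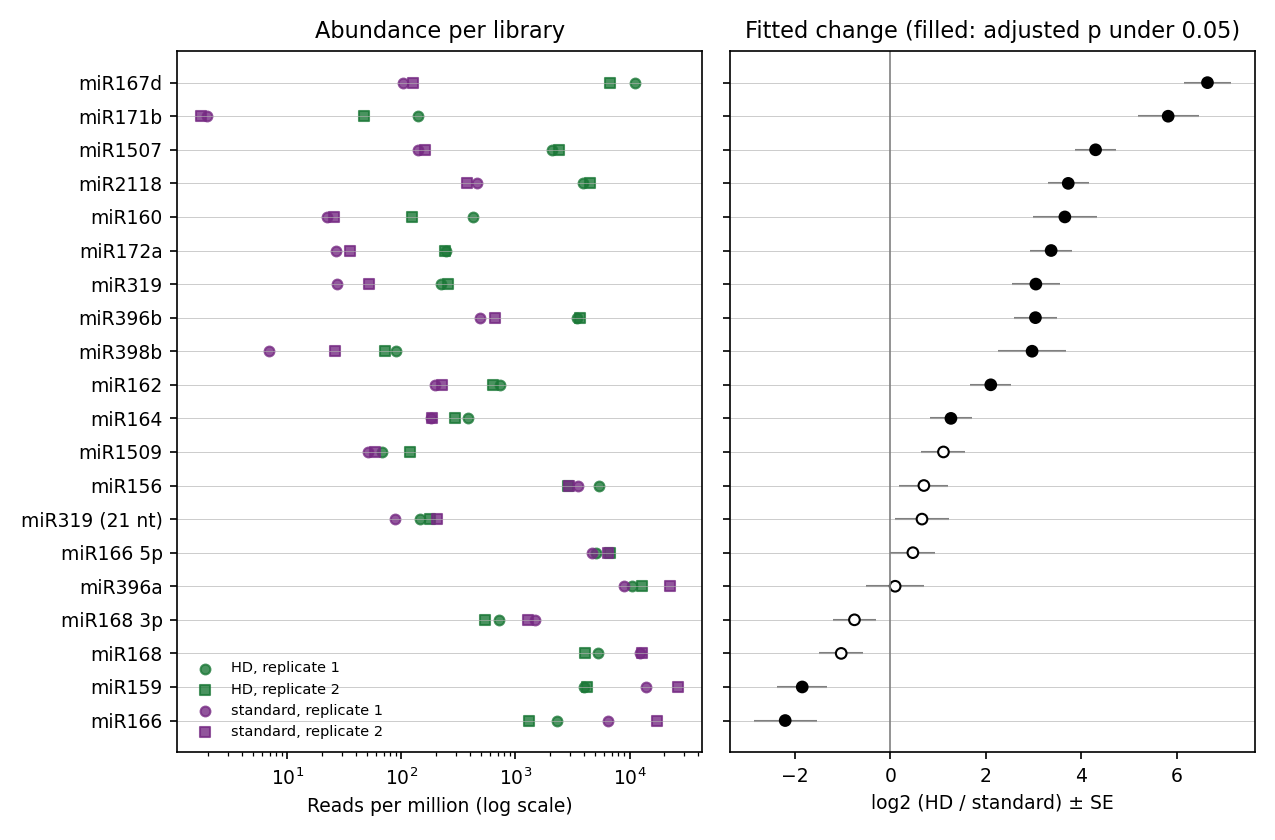
Left, RPM (log axis) of the 20 most abundant list members in each library, 1 point per library. Right, log2 of HD over standard with its SE from limma voom, filled where the adjusted p was under 0.05, running from -2.20 for miR166 to 6.65 for miR167d; the direction of miR396a turned with library totals as the scaling.

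Several of these calls were lost when 1 library was left out. Leaving out a library also changed which sequences passed the read filter, and with them the scaling. The median log2 change across tested sequences was 0.33 without standard replicate 1 and 0.44 without standard replicate 2, against -0.14 with all libraries. The losses and moves below therefore cannot be credited to the library alone. Without standard replicate 2, miR159 and miR166 no longer passed (limma adjusted p = 0.133 and 0.101), nor did they when only sequences with at least 50 reads in 2 libraries were tested (0.109 and 0.0878). Without standard replicate 1, miR162, miR164 and miR398b were lost (0.0977, 0.422 and 0.0851), and 10 of 13 named miRNA past the threshold moved by over 1.5 times, miR319 to log2 2.06 and miR167d to 5.99 among them. The values of miR171b and miR160 went from log2 5.07 and 2.80 without HD replicate 1 to 6.84 and 4.77 without HD replicate 2. With variants summed in that way, miR171b went to log2 3.50, and miR162 and miR164 no longer passed (0.108 and 0.136). The sum for miR396b also holds miR396a, and that for miR319 (log2 1.48) also holds its 21-nt form, so neither tests the form alone. The 2 forms of miR1509 share 1 sum as well, which lay at log2 -0.21 (limma adjusted p = 0.694). Of the members named after their values were seen, miR1510 no longer passed without HD replicate 2 (log2 -1.04) or standard replicate 2 (log2 -1.69, against -1.60 with all libraries). It was also lost with the filter of 50 reads (limma adjusted p = 0.137). With that filter miR157 was lost as well (0.0865), and miR396 3p was lost without standard replicate 1 (0.0501). The call of miR164 was also lost with library totals only (0.102), without HD replicate 1 (0.0954) and without standard replicate 2 (0.238).

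The most abundant sequences of HD libraries were miR396a, miR167d and TTTCCAATTCCACCCATTCCTA, a 22-nt sequence that shares its last 16 bases with miR2118. The last had 8531 ± 733 RPM in HD and 526 ± 55.1 in standard libraries, a 16.2-fold difference (log2 4.42 ± 0.43, limma adjusted p = 0.000364). In standard libraries the leading sequences were miR159, CGGGGCGACATGGGACAAC and miR396a. The 19-nt CGGGGCGACATGGGACAAC had 16194 ± 3080 RPM there and 1773 ± 537 in HD libraries, 9.13-fold fewer (log2 -2.81 ± 0.48, limma adjusted p = 0.00334).

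Most of the largest changes were in sequences that one adapter type did not read at all. Against a floor of 3 reads over the group, 0.0532 RPM for standard and 0.0926 for HD libraries, the 27-nt CTGACTGGCCAGCTCACGGCTGTCCAG was at least 64706-fold higher in HD libraries. It was read at 3445 ± 736 RPM there, and its origin was not determined. The 24-nt ACATGTACCACCCCATGTGGCAAT, at 103 ± 38.2 RPM, was at least 1941-fold higher in HD libraries. Of GCTGTAGTTTAGTGGTAAGAATTCCACG there were 4580 HD reads and 1 standard read, a ratio of 7963 between pooled reads over pooled depth, with an exact 95% interval of 1428 to 314572. That ratio was 11266 without HD replicate 1 and 3810 without HD replicate 2. This sequence holds GAATTC, a part of the 3′ adapter. So did 3.74% of sequences higher in HD, 2.60% of those higher in standard libraries and 2.24% of those not past the threshold. Whether the match to the adapter affected its counts was not tested. The 21-nt CGGATTGGCTGAAGGATTCCA had 1474 ± 74.7 RPM in HD and 0.392 ± 0.0958 in standard libraries, 3757-fold fewer. GAGTTCTACAGTCCGACGATCGAGG, at 141 ± 145 RPM and at least 2653-fold higher in HD libraries, begins with the end of the 5′ adapter. Its bound was 733-fold without HD replicate 1 and 4573-fold without HD replicate 2. Intervals and floors cover counting error only, since reads copied by PCR are not independent molecules.

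A pair of variants went opposite ways. AGCCTATGATGATAAAACA was read at 212 ± 207 RPM in HD libraries and in no standard library, at least 3984-fold higher. That bound was 1239-fold without HD replicate 1 and 6728-fold without HD replicate 2. AGCCTATGATGATAAAACATATC, which is 4 bases longer at the 3′ end, was read at 617 ± 443 RPM in standard libraries and in no HD library, at least 6664-fold higher (3276-fold without standard replicate 1 and 10052-fold without standard replicate 2). Summed over their first 18 bases the counts were 212 ± 206 and 619 ± 445. TCAACGAGAACAGAAATCTCGTG, at 629 ± 406 RPM and at least 6795-fold higher in standard libraries (3695-fold without standard replicate 1), also had a shorter main form in HD libraries, TCAACGAGAACAGAAATCT, at 70.9 RPM against 2.55 in standard libraries. The other 4 named sequences higher in standard libraries, of 33 to 35 nt, exceeded the 32-nt limit of the HD files, which alone leaves them out. They were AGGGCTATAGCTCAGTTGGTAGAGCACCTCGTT (614 ± 160.7 RPM), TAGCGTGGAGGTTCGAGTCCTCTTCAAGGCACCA (347 ± 149), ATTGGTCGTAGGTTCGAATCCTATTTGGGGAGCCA (209 ± 54.3) and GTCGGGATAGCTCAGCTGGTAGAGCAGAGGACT (192 ± 13.6). In HD libraries the main form of each was its first 32 bases, at 899.9, 21.9, 25.4 and 64.4 RPM in the same order. Those 32-nt forms stood at 544, 1.62, 0.714 and 40.2 RPM in standard libraries. Whether the HD reads of 32 nt were longer RNA cut at the limit was not tested.

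Fragments from the 5′ ends of tRNA were counted at any length, so those of 33 to 40 nt could enter for standard libraries only. The folds were not recomputed for reads up to 32 nt. The fragments differed in direction. Those of tRNA-Gly-GCC stood at 1778 ± 93.3 RPM in HD and 452 ± 315 in standard libraries, 3.93-fold higher with HD adapters (SD, n = 2 each, exact permutation p = 0.33). That fold was 7.74 without standard replicate 1 and 2.64 without standard replicate 2. Those of tRNA-Ala stood at 138 ± 36.2 against 578 ± 7.17 RPM, 4.20-fold higher with standard adapters (exact permutation p = 0.33). The tRNA-Arg fragments stood at 166 ± 1.44 against 286 ± 66.9, and tRNA-Gly-TCC at 10.9 ± 7.79 against 5.81 ± 2.48, a fold of 1.88 that was 0.936 without HD replicate 2. All listed fragments together stood at 2092 ± 47.9 and 1321 ± 243 RPM. Reads with 12 or more bases of an adapter made up 6.71% and 1.20% of the HD libraries and 0.218% and 0.190% of the standard libraries. Of the miRNA of other species, those of *Arabidopsis* had 1 and 2 reads in HD and 2 and 1 in standard libraries, and those of animals had 2 reads in HD replicate 1 and 0 elsewhere.

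The adapters differ at the ends that are ligated, so the end bases of favoured sequences were compared. The last base was G in 25.6% of sequences higher in HD libraries, in 15.3% of all tested and in 7.40% of those higher in standard libraries. It was T in 20.4%, 23.98% and 34.3% in the same order. The third base from the 3′ end was A in 29.8%, 37.8% and 42.3%, and T in 17.4%, 10.9% and 7.57%. At the 5′ end the first base was G in 28.0%, 21.1% and 16.0%, and C in 12.9%, 18.7% and 23.4%. Of 48 tests of a base at the first or last 3 positions, 47 had an adjusted p under 0.05 by Fisher's exact test, over sequences that are not independent.

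**Figure D3:**
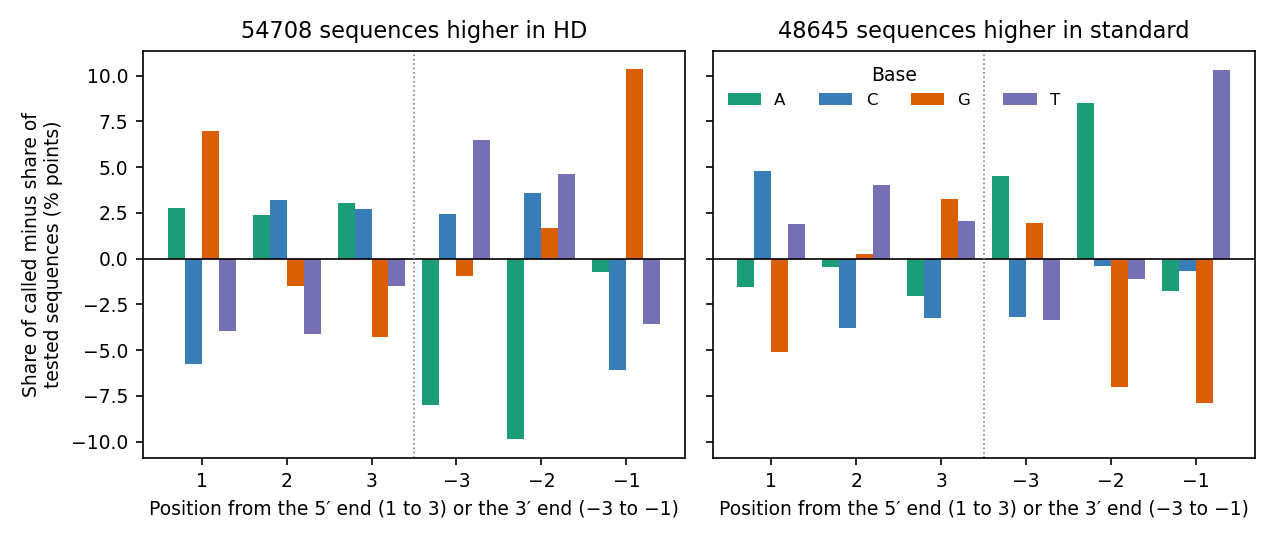
Difference in percentage points between called and tested sequences in the share of each base at the first and last 3 positions, for the 54708 sequences higher in HD (left) and the 48645 higher in standard libraries (right). A last G stood at 25.6% of the former and 7.40% of the latter, against 15.3% of the tested sequences.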

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

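The settings chosen after seeing the data were limma-trend, reads without adapter bases, the crossed block and 3 settings of the class test. The planned second count test and a match to the genome were not run. Sequence calls were 103353 with the settings reported, 104564 with median-of-ratios, 109556 with library totals, 98478 with reads of 20 to 25 nt, 115837 with limma-trend and 109002 without adapter reads. Those higher in HD went from 52.9% of calls to 45.7% with library totals, 48.5% with 10 reads over the 4 libraries, 49.9% with 50 reads in 2 libraries and 49.8% with limma-trend, so the majority turned in these 4. A filter of 10 reads over the 4 libraries gave 312413 calls of 719345 tested, and one of 50 reads in 2 libraries 18346 of 30480, since more or fewer sequences were tested. With 1 library left out, calls ranged from 92922 of 250035 tested (without HD replicate 2) to 124323 of 262495, and 63367 to 78428 of the 103353 were called again. Listed members called were 27 of 38 tested. The same settings called 25 (all higher in HD, with 50 reads in 2 libraries) to 31 of 34 to 39 tested, variants summed over 18 bases 21 of 33, and leaving out a library 19 to 28 of 38. Class calls went from 43 to 9 over 17 to 32 nt, where 11 of the 43 lay, so shorter classes lost calls too, and to 0 there with 1 prior spread (9 at an unadjusted p under 0.05 by limma). They were 34 with that spread over all lengths, 44 with TMM, 62 for distinct sequences, and 41 to 53 with a library left out. Of 48 end-base tests, 36 to 48 passed. Opposite in direction were 3 with 21-nt sequences only, 1 with at least 4-fold changes, 2 with 1 sequence for each shared run of 16 bases and 0 with 24-nt sequences only.

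HD minus standard differences ranged, without each library, from 1.43 to 4.79 percentage points for 24 nt, -6.90 to -0.73 for 21 nt, 7.53 to 9.14 for distinct sequences, -7.90 to -3.27 for the 10 most abundant and -3.79 to 0.115 for listed miRNA. The 24-nt difference of 3.11 was 1.43 among reads of 20 to 25 nt, 0.397 without the 10 most abundant sequences and 4.62 without reads holding adapter bases. The 21-nt difference turned to 1.62 without the 10 most abundant sequences, and that of distinct sequences to -3.38 with those read at least 2 times at each library's full depth. Against log2 0.10, miR396a stood at -0.294 with library totals, -0.0930 with 10 reads over the 4 libraries and -1.09 without standard replicate 1, and ranged to 0.59 with a library left out. With a library left out miR166 5p ranged from -0.28 (without standard replicate 1) to 0.71 and the 21-nt miR319 from -0.47 (the same library) to 1.09. With 50 reads in 2 libraries miR168 3p was at 0.0259, and with variants summed miR1509 at -0.21. None of these named members had passed the threshold, and the cause was not tested. The sum of miR1509 also holds its 21-nt form, which had passed, so that call turned with it. Of members named after their values were seen, miR1510 missed the threshold in 3 settings, miR157 in 1 and miR396 3p in 1. Other values of named sequences under planned and added settings were 294 alike, 7 that lost and 12 that gained the threshold; with a library left out they were 125, 7 and 1.

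With the replicate number as a block there were 106190 sequence calls, 27 listed calls and 44 class calls. The numbers were not shown to pair libraries: differences between replicates correlated at r = 0.064 over 168837 sequences and at -0.112 over 2423 with at least 10 RPM. A block with crossed numbers gave 100600 and 27 calls.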

Other observations

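Chosen only after their results were seen were the tests on 4-base end shifts and on 4 added bases, the comparison with shuffled adapters, and the values on added bases and duplexes. Reads of listed miRNA with 1 extra base at the 3′ end differed between the adapter types in number and in the base added. Summed over the lists, such reads made up 11.8% ± 0.981 of exact and extended reads in HD and 2.33% ± 0.631 in standard libraries (SD, n = 2 each, exact permutation p = 0.33). Of the 116610 and 118181 extended reads in HD libraries, 93917 and 86342 were of miR167d, which is far more abundant there, although its own extended share was lower in HD libraries (39.2% against 86.2%). Without it the shares, which weigh each member by its reads, were 3.55% ± 0.271 and 1.34% ± 0.382 (exact permutation p = 0.33). Its added base was G in 86.0% and 77.0% of HD and in 24.1% and 7.05% of standard reads, and A in 13.5% and 22.4% against 60.1% and 76.7%. An added G was also more frequent for miR396a, at 33.5% and 44.7% in HD against 0.195% and 0.0713% in standard libraries, and for miR156, at 23.8% and 30.9% against 0.355% and 0.154%. Of 22 members with enough reads, 12 had a higher mean extended share in HD libraries, 9 of them with both HD libraries above both standard libraries. The reverse, both HD libraries below both standard libraries, held for miR168, miR167d, miR162, miR164, miR172a, miR1509, miR396 3p, miR398a and miR169b. The members thus split both ways.

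Duplex partners were seen with both adapters. The search covered only a part of the distinct sequences. At 24 nt it held 385857 and 395297 sequences in HD and 425289 and 451597 in standard libraries. A partner was a complementary sequence of the same length, offset to leave the 2-nt 3′ overhang of Dicer products. It was found for 5.42% and 5.35% of these 24-nt sequences in HD and 4.80% and 5.24% in standard libraries. Among overhangs of 0 to 5 nt the next highest was 5 nt, at 4.76%, 4.71%, 4.18% and 4.57% in the same order. For 21-nt sequences the 2-nt overhang was found for 13.8% and 13.6% in HD and 11.9% and 12.7% in standard libraries.

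The first pattern weighed is the difference between adapter types across sequences. A shift between 3′ variants is argued against as its whole cause, because the listed miRNA called kept a median of 82.9% of their log2 change (quartiles 64.4% to 91.1%) when variants sharing 18 bases were summed, and 18 members whose sum held no other list member a median of 87.1%. Base preference at the ligated ends may be a large part, and the test cannot decide whether it is the whole cause. The first and last 3 bases predicted 32.7% of the variance among 69776 called 24-nt sequences (31.8% to 33.7% over 10 parts). This was below the limit set beforehand for the whole cause. Models of 6 inner bases predicted 6.31% to 10.2%, and all 24 bases 50.4%. Those models include pairs of bases, and without pairs all 24 bases predicted 28.3%. How much of the variance was noise between libraries was not estimated. Overlapping sequences could also fall in different parts. A candidate contribution is folding of the RNA onto the fixed adapter bases, since RNA that lost less stability with them, relative to shuffled adapters, was read more in standard libraries (median gains of -1.25 and -0.71 kcal/mol in sequences higher in HD and in standard libraries, Spearman rho = -0.136 across 6000 sequences, bootstrap 95% interval -0.162 to -0.110). With 10 shuffled adapter pairs rho lay between -0.0726 and 0.0827. The relation is weak, sequences are not independent replicates, and no biological explanation was tested.

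The second pattern is listed miRNA flanked by 4 extra bases on each side, read 1140 and 1058 times in the standard libraries and 1 and 0 times in the HD libraries. Bases of the precursor are argued against, since 2198 such reads carried 1900 distinct flank pairs, or 0.864 per read. Reads of HD libraries counted in standard libraries remain a candidate source: over 23 members the proportions among these reads lay a median of 0.747 log2 units from those of HD libraries and 3.09 from those of exact reads in the same standard libraries, a difference of 2.35. There were 2198 such reads beside 4373412 exact reads of listed miRNA, and as longer sequences they are not among the exact counts. Where such reads would arise was not tested.

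The third pattern is sequences whose 3′ end lies 4 bases further in standard than in HD libraries, as for AGCCTATGATGATAAAACA. There were 458 such pairs, 1.39 times the mean of 329 for pairs 2, 3, 5 and 6 bases apart. That ratio lay within the limit set for natural variation of RNA ends. Pairs that went the opposite way numbered 629 at 4 bases, against 271, 374, 247 and 222 at 2, 3, 5 and 6 bases. The limit was not applied to that direction, which peaked at 4 bases, so natural variation was not shown to suffice. A site resembling the start of the 3′ adapter inside the RNA stays open for part of the 458 pairs. Where HD reads ran past the longer end, the next 3 bases were TGG in 23.4% of 394 pairs, against 2.99% to 7.43% at other distances, a share between the limits set for and against that explanation.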
